A study of Mus musculus with 16 samples.

How the data were processed

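Chromatin accessibility was measured by Omni-ATAC, an ATAC-seq protocol in which a transposase inserts sequencing adapters into open chromatin, in 16 libraries from spleens of C57BL/6 mice. The genotype label and the sample title put each library into 1 of 4 groups of 4: Smarca4+/+ (WT) or Smarca4+/- (HET) cells labelled CB or CC. The abbreviations are not spelled out in the labels and are read here as centroblast and centrocyte, and the labels give no sort gate. The replicate numbers run from 1 to 4 in every group. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

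The values used were raw counts per peak, as deposited by the authors in a table of the whole series with 82188 peaks, each 501 bp wide, on 20 chromosomes, and a peak set shared by all libraries. The submitters' processing notes name FastQC, BWA, deepTools, R 4.2.1 and the mouse genome build mm10. How the peaks were called and how reads or transposition events were counted is not given in the sources used here. Every count column matched the title of 1 sample. Totals ranged from 31696941 to 38798802 counts in WT CB, 38716281 to 51011923 in HET CB, 3494356 to 3750936 in WT CC and 5310327 to 7474760 in HET CC. The smallest library held a median of 22 counts per peak and the largest 347. Counts from PCR-amplified libraries are not independent molecules, so precision from counting covers counting error only.

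Each peak was tested, and peaks were also summed per gene. A peak was assigned to the protein-coding gene whose span was nearest to its middle, up to 50 kb away, with the coordinates of the RefSeq table of GRCm38.p6, the assembly that mm10 denotes; 74773 peaks (91.0%) were assigned, to 15052 of 21900 genes. A peak inside a gene span counts for that gene, so a gene value is the accessibility around a gene and not its transcription, and a distal peak may act on another gene. The table gives no strand, so the nearest gene span replaced the nearest transcription start site of the plan, and the share of counts within 1 kb of either gene end replaced the share at promoters. Peak middles lay within 1 kb of a gene end in 21.6% of peaks, against 5.9% after all peaks were shifted by 10 kb. Motif tests and corrections for GC content need the genome sequence, which was not used here, and were not run.

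Differential accessibility was tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M-values (TMM) scaling, filterByExpr, which removed 0 peaks and 0 genes, robust quasi-likelihood fits of all 16 libraries with 1 coefficient per group, and Benjamini-Hochberg adjustment over all peaks or all genes. An adjusted p below 0.05 is called a change. All adjusted p-values of peaks and genes come from these quasi-likelihood tests unless another tool is named. The 5 comparisons were HET against WT in CB and in CC, CC against CB in WT and in HET, and the interaction, which is the HET effect in CC minus that in CB. Values per library are CPM, counts scaled to a common TMM-adjusted library total, given as mean ± SD over 4 libraries, and log2 fold changes carry the standard error (SE) of the fit.

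Gene lists were written from textbook knowledge: the dark zone program, light zone program, germinal center program, memory B cell program, plasma cell program, MYC and biomass growth, cell cycle, NF-kB and CD40 signaling, B cell receptor signaling, antigen presentation, the BAF chromatin remodeling complex, B lymphoma tumor suppressors and chromatin regulators, interferon response and naive follicular B cell markers, with markers of T cells, NK cells, myeloid cells, erythroid cells and megakaryocytes, and stromal and follicular dendritic cells. Lists overlap: of the measured members, 11 of 14 naive follicular and 8 of 20 memory genes also stand in another list, so their results are not separate. The 19 lists hold 370 distinct genes, of which 364 were in the reference and 317 had a peak. They were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes.

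The named genes and peaks follow a rule: per comparison, the 5 peaks and 5 genes with the largest positive and negative log2 fold change among calls whose mean accessibility lies above the median and whose 4 against 4 library values do not overlap; up to 4 members per list with the smallest p and the best peak of each; Smarca4; and Cxcr4, Cd83, Cd86, Bcl6, Myc, Irf4, Prdm1, S1pr2, Ccr6 and Spi1. Some genes that the rule selects are not reported here. The groups, comparisons, tests, gene list themes, the rule for names and most alternatives were fixed before the data were examined. The X-linked loci Firre, Xist and 4933407K13Rik and the escape genes were chosen after values had been seen.

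The position of each library between the mean of WT CC (0) and of WT CB (1) was estimated over all peaks as a ratio of covariances in which different WT libraries stood in each factor, and groups were compared by two-sided exact permutation tests over 70 splits, for which 0.0286 is the smallest possible p. The HET effect and the change from CB to CC share WT libraries. Their correlation was therefore computed with the WT libraries of the shared cell type split into separate pairs in 6 ways, and beside 20 simulations of unchanged HET libraries. List medians were set beside 10000 random lists matched on CB accessibility, an addition made after the results were seen.

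The procedures were tested on simulated counts drawn from the means and sizes of the real libraries. Of genes changed 2-fold, 99% were recovered in the simulated CB comparison and 93% in CC, and of genes changed 1.5-fold 90% and 74%, with 0 false calls in CB and 48 in CC. Among peaks changed 2-fold, 92% were recovered in CB and 51% in CC, with 1 and 37 false calls. Fits of the 8 CC libraries alone gave 4 false calls among genes and 3 among peaks. The biological coefficient of variation, estimated within groups, was 7.2% in WT CB, 5.6% in HET CB, 16.4% in WT CC and 15.2% in HET CC, against 8% in the shared fit. The largest error of a simulated position was 0.044, and of the 19 lists the 1 raised 1.3-fold was called and 0 others. Simulated genes were drawn independently, so this does not test the list calls against correlation between genes.

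Alternatives tried were other scalings (size factors of DESeq2 1.42.0, total counts alone, loess offsets), no filter and a mean of at least 2 CPM, an adjusted p below 0.01, a tested minimum fold of 1.2, non-robust estimation, the DESeq2 Wald test, only the libraries of the compared groups, the replicate number as a block, assignment within 10 kb, peaks in place of gene sums in the list tests, and leaving out each library in turn. Added later were limma voom with a variance weight per group, thinning of every library to the smallest total, a 2-level term among the CB libraries, the position as a covariate, and omission of the HET CC libraries 2 and 4. Tables were handled with the R package data.table, version 1.17.8, and in Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.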

Results

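Accessibility was compared between cells labelled CB and CC of wild-type (WT, Smarca4+/+) and heterozygous (HET, Smarca4+/-) mice, with 4 libraries in each of 4 groups. The labels are read here as centroblasts (CB) and centrocytes (CC), a reading that the marker loci below do not settle. Smarca4 encodes BRG1, an ATPase of the BAF chromatin remodeling complex, and the series asks how its loss changes accessibility in germinal center B cells. The first principal component of all peaks held 66.3% of the variance and the second 5.9%. Library totals ranged from 31696941 to 51011923 counts in CB and from 3494356 to 7474760 in CC. Every CC library was thus sampled more thinly than every CB library, and HET CC libraries held 1.73 times the counts of WT CC on average. Pearson correlations between replicates were 0.989 to 0.995 within the CB groups and 0.909 to 0.95 within the CC groups.

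The Smarca4 locus, 9 peaks within 50 kb of the gene, was accessible in every library. In CPM of the summed peaks, the WT CB libraries stood at 195.99, 184.83, 196.16 and 183.25 and the HET CB libraries at 176.24, 180.21, 176.62 and 174.87. The WT CC libraries stood at 152.84, 164.64, 155 and 184.73, and the HET CC libraries at 139.84, 156.57, 164.71 and 156.26. The log2 change of HET against WT was -0.10 (SE 0.045, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.412) in CB and -0.09 (SE 0.058, adjusted p = 0.373) in CC, with an interaction of 0.01 (adjusted p = 0.964). In WT the locus fell from CB to CC (log2 -0.21, SE 0.053, adjusted p = 0.000837), and in HET as well (-0.20, SE 0.05, adjusted p = 0.000767). A peak 96 bp from the gene rose in CC (0.76 in WT, adjusted p = 9.93e-13), while 4 intragenic peaks fell, with log2 changes from -1.22 (2.53e-09) to -1.55 (1.03e-07). The labels do not say which part of the gene is deleted, so these peaks do not test the genotype.

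Among WT libraries, 19 of 23 loci of the germinal center program, the genes that set the identity of B cells in this reaction, were less accessible in CC than in CB (camera adjusted p = 5.59e-06, and adjusted p = 0.0582 with an estimated correlation). Gcsam, a germinal center signaling adaptor, fell from 177.1 ± 12.0 to 55.5 ± 6.77 CPM (mean ± SD, n = 4, log2 -1.67, SE 0.098, adjusted p = 1.97e-15). S1pr2, a receptor that retains B cells in the follicle, fell from 144.5 ± 6.97 to 48.7 ± 11.7 (-1.57, SE 0.096, 6.83e-15). Members of the memory B cell program rose (12 of 20, camera adjusted p = 0.00743, and adjusted p = 0.356 with an estimated correlation), and so did 13 of 16 T cell and 6 of 10 NK cell marker loci. Klf2, a transcription factor of trafficking, rose by 0.84 (2.72e-14), and Il7r, the interleukin 7 receptor, from 5.90 ± 0.682 to 35.4 ± 6.85 CPM (2.58, SE 0.18, 4.41e-15). The largest rises by the rule were at Slc16a7, a monocarboxylate transporter, from 26.4 ± 1.42 to 210.1 ± 10.7 CPM (2.99, SE 0.09, 1.53e-21), Dse (2.77), Prkch, a protein kinase C (2.14), Cobll1 (2.06) and Fyb (2.06). The largest falls were at Tgfa (-1.85), Dnase1 (-1.81), C8a (-1.75), Cfap74 (-1.72) and Ackr4, an atypical chemokine receptor (-1.71). Of these genes Tgfa had the largest adjusted p, 4.89e-13.

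Falls in the germinal center program, where 1 further member rose, included Nuggc (-0.96) and Gna13, a G protein subunit that confines B cells (-0.60). B cell receptor signaling had 16 falls and 1 rise among 24 (camera adjusted p = 0.000735, and adjusted p = 0.253 with an estimated correlation). Examples were Bank1 (-0.53) and Plcg2 (-0.49). The median of this list, -0.245, lay within the middle 95% of random lists matched on CB accessibility (-0.295 to 0.052). The dark zone program had 9 falls and 3 rises among 15 (0.0208, and adjusted p = 0.0697 with an estimated correlation). Cxcr4, the chemokine receptor of the dark zone (-0.33, SE 0.039, adjusted p = 1.32e-09), and Ccnd3 (-0.29) fell. The dark zone median, -0.199, lay within its matched range as well (-0.34 to 0.098), while that of the germinal center program, -0.391, lay below (-0.298 to 0.057) and those of the memory (0.335) and naive lists (0.238) above theirs (upper ends 0.113 and 0.105). In the memory B cell program 12 members rose and 3 (Cd80, Nt5e and Pdcd1lg2) fell of 20 (0.00743, and adjusted p = 0.356 with an estimated correlation). Bcl2, a survival factor, rose by 0.55 and Vim by 0.99. Naive follicular B cell markers had 7 rises and 2 falls (Cr2 and Foxp1) among 14 (0.0276, and adjusted p = 0.38 with an estimated correlation). That call ended without WT CC replicate 4 (0.0534). Adjusted over the list alone, these counts were the same except for memory, with 13 rises.

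The light zone program, genes raised where B cells receive T cell help, did not move one way: 11 members rose and 11 fell of 29 (camera adjusted p = 0.901, median -0.001, mean 0.044). Cd86, a costimulatory ligand, fell from 309.5 ± 11.3 to 179.4 ± 2.97 CPM (-0.79, SE 0.045, adjusted p = 1.23e-17) as did Cd83 (-0.21, 0.000144), while Rel, an NF-kB subunit, rose by 0.47 (3.63e-12) and Myc by 0.17 (0.0024). The fall of Cxcr4 goes with reading CC as centrocytes, but the falls of Cd86 and Cd83 and the rise of naive markers do not. Whether the CC hold B cells from outside the germinal center was not tested. Plasma cell genes had 5 rises and 11 falls among 17 (0.202). Prdm1 rose by 0.47 (3.36e-10), while Jchain (-1.33), Slamf7 (-0.83) and Irf4 (-0.13, 0.0258) fell. The Irf4 call ended with total counts as the scaling and without WT CB replicate 1 or 3 or WT CC replicate 1, 2 or 3. Bcl6 (0.06, 0.361), Ccr6 (0.05, 0.329) and Spi1 (-0.12, 0.0596) did not pass the test. Lists that did not pass as a whole were MYC and biomass growth (9 rose and 6 fell of 20, 0.794, median 0.055, mean -0.025), cell cycle (7 and 14 of 29, 0.529, with Ccne1 at 0.51 and Plk1 at -0.95) and NF-kB and CD40 signaling (11 and 8 of 23, 0.342, with Nfkb1 at -0.37). Nor did antigen presentation (2 and 3 of 7, 0.649), the BAF complex (5 and 13 of 28, 0.178), B lymphoma tumor suppressors and chromatin regulators (9 and 12 of 27, 0.547) or interferon response (9 and 2 of 20, 0.222, with Rsad2 at 1.36). Adjusted over the list alone, 8 cell cycle members rose, antigen presentation had 3 rises and 4 falls, and the tumor suppressors 10 and 13.

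Markers of other cell types also differed between CB and CC in WT. Of 16 T cell loci, 13 rose and 3 (Cd2, Cd247 and Cd4) fell (camera adjusted p = 3.66e-05, and adjusted p = 0.0611 with an estimated correlation). Their median log2 change was 1.11. Bcl11b, a T cell transcription factor, went from 10.1 to 49.5 CPM (2.30, 1.61e-18). Tcf7 rose by 1.68 and Cd8a, a T cell coreceptor, from 1.35 to 11.5 CPM (3.09, SE 0.24, 7.66e-14). Among 10 NK cell loci 6 rose and 1 (Tbx21) fell (0.0128, and adjusted p = 0.0803 with an estimated correlation). Nkg7 (1 peak) rose by 3.35 (SE 0.27, 9e-14), Klrk1 by 2.72 and Gzmb by 2.42. Stromal and follicular dendritic markers had 7 rises among 11 (0.00743, and adjusted p = 0.0697 with an estimated correlation). Examples were Col1a2 (1.76) and Pecam1 (1.11). Myeloid markers (10 rose and 4 fell of 15, 0.178, with Fcer1g at 2.75 and Tyrobp at 1.13) and erythroid and megakaryocyte markers (3 and 3 of 8, 0.717, median 0.095, mean -0.013) did not pass.

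At peak level, 24850 peaks were higher and 22729 lower in WT CC than in WT CB (57.89% of 82188, median absolute log2 of the called 0.91). Of 15052 genes, 4757 were higher and 4777 lower. By the rule, the largest rises included peaks 59 bp from Arrdc4 (3.58, adjusted p = 2.04e-25), 42 bp from Slc16a7 (3.17, 5.45e-27) and within Selp (3.15). The largest falls included peaks within Scn11a (-3.52, 1.32e-12) and 44328 bp from Gpatch2 (-3.18, 1.54e-15). Peaks within 1 kb of a gene end took 45.43 ± 0.38% of the counts of WT CC and 41.87 ± 0.25% of WT CB (difference 3.57, two-sided exact permutation p = 0.0286, the smallest that 70 splits allow).

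**Figure D1:**
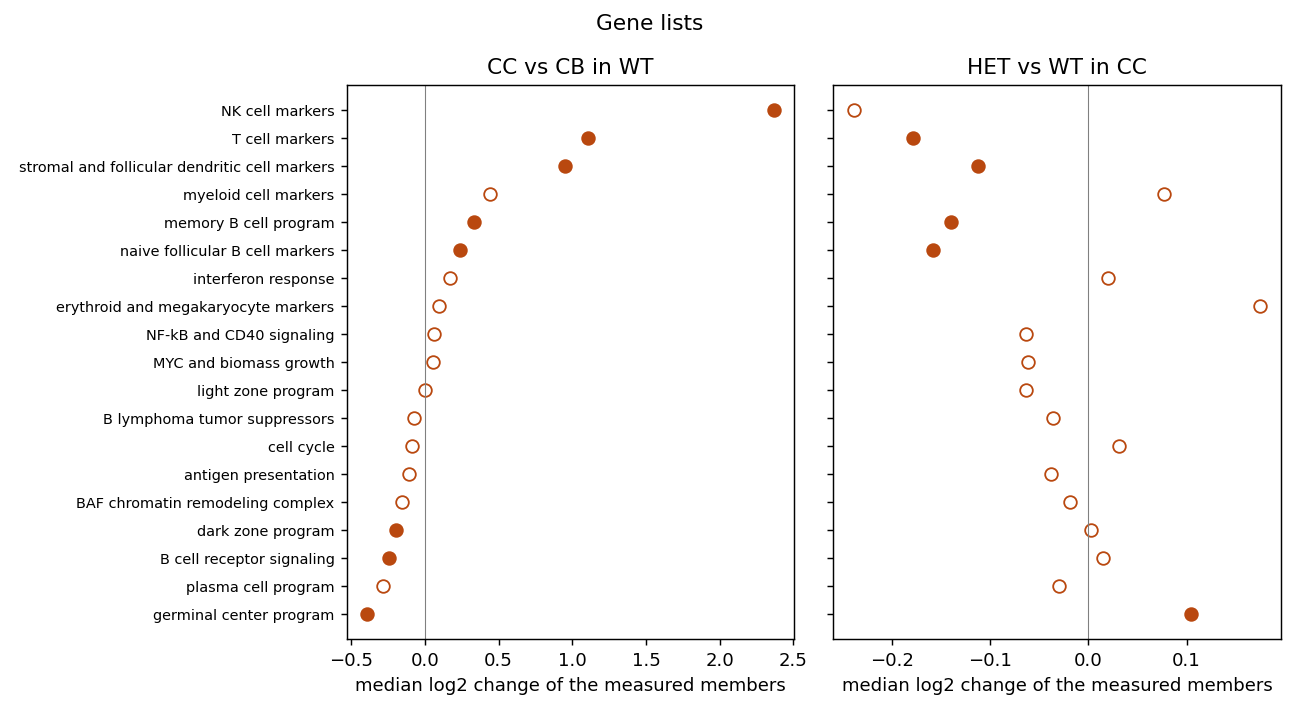
Median log2 change of the measured members of each of the 19 gene lists (x axis) for CC against CB in WT (left) and HET against WT in CC (right). Filled points mark lists with a camera adjusted p below 0.05 at an inter-gene correlation of 0.01; no error bars are drawn.

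In HET libraries the same loci moved between CB and CC, at several of them by less. Slc16a7 rose by 3.25 (SE 0.09, adjusted p = 1.39e-22), Dse by 2.67, Prkch by 2.28, Fyb by 2.12 and Chrm3, a muscarinic receptor, by 1.96. Tgfa (-1.55), Dusp14 (-1.40), Ccdc190 (-1.38), Pm20d1 (-1.35) and Dnase1 (-1.34) fell most. The germinal center genes Gcsam (-0.95, SE 0.081, 1.27e-11) and S1pr2 (-0.91, SE 0.08, 2.73e-11) fell. So did Cd86 (-0.61, 1.9e-15), Cxcr4 (-0.36, 1.23e-10), Irf4 (-0.19, 0.000596) and Spi1 (-0.23, 0.000114). Prdm1 (0.34, 1.57e-07) and Bcl6, the repressor that maintains the germinal center (0.16, 0.00738), rose. The Bcl6 call ended without HET CC replicate 3. Cd83 (-0.02, 0.785), Myc (0.04, 0.459) and Ccr6 (0.07, 0.2) did not pass. Over all genes, the changes from CB to CC in WT and in HET were correlated at 0.938 across genes, which are not independent replicates, with a slope of 0.881 for HET on WT. Noise in the WT values lowers this slope, so it does not measure a smaller change in HET. In both genotypes, 4020 genes were higher and 4028 lower, against 1479.69 and 1515.42 expected by chance.

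Of the 23 germinal center members 18 fell and 3 rose in HET CC (camera adjusted p = 7.08e-05, and adjusted p = 0.0687 with an estimated correlation). Of 24 B cell receptor signaling members 15 fell and 1 rose (0.000809, and adjusted p = 0.258 with an estimated correlation). The memory B cell program had 12 rises and 4 falls (0.0411, and adjusted p = 0.433 with an estimated correlation). That call ended without HET CC replicate 1 (0.0858) or 3 (0.0614). Dark zone (3 rises and 8 falls, 0.0674) and naive follicular genes (8 and 4, 0.173) did not pass. Markers of other cell types rose here too. They were 13 of 16 T cell loci, with 2 falls (2.04e-05, and adjusted p = 0.0687 with an estimated correlation), and 7 of 10 NK cell loci, with 1 fall (0.00755, and adjusted p = 0.0824 with an estimated correlation). Stromal loci had 7 rises among 11 (0.0165, and adjusted p = 0.0842 with an estimated correlation). Among the myeloid cell markers, 7 of 15 rose and 2 fell (0.0411, and adjusted p = 0.0842 with an estimated correlation), a call that ended without HET CC replicate 3 (0.0532). Cd8a rose by 3.22, Nkg7 by 3.30 and Il7r by 2.71 (5.17e-16). Median and mean differed in sign for the light zone (-0.015 and 0.027), tumor suppressor (0.029 and -0.042) and MYC (0.003 and -0.014) lists. In all, 25301 peaks were higher and 23058 lower in HET CC than in HET CB, and 4682 and 4775 genes.

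In the fit of all 16 libraries, heterozygous CB differed from WT CB at 84 genes, 79 of them lower, and at 106 peaks, 104 of them lower. The CB libraries fitted alone gave 491 genes and 1076 peaks (416 higher, 660 lower). The coefficient of variation of 8% in the fit of all 16 libraries lies above the 7.2% of WT CB and 5.6% of HET CB. That fit can therefore be the stricter one in CB. Slc16a7 fell from 26.4 ± 1.42 to 15.9 ± 0.972 CPM (log2 -0.73, SE 0.088, adjusted p = 4.01e-05) and Chrm3 from 51.2 to 37.2 (-0.47, SE 0.072, 0.000966). Gm5127 (-0.44, 0.000427), Chn2, a Rac GTPase-activating protein (-0.39, 0.00279), and Dse (-0.38, 0.0344) also fell. Fcer2a, the low-affinity IgE receptor CD23 of naive B cells, fell from 49.4 ± 2.02 to 40.6 ± 1.07 CPM (-0.29, SE 0.056, 0.00787). Klrk1, an NK cell receptor, fell from 3.56 to 2.20 (-0.70, 0.0354). Rises were small. Il10, an anti-inflammatory cytokine, rose from 125.3 ± 4.79 to 147.0 ± 4.72 (0.23, SE 0.058, 0.0487), and Ryk (0.21, 0.0384), Caprin2 (0.19, 0.0263) and Cry1, a circadian repressor (0.18, 0.0384), rose. The Il10 and Ryk calls ended in each of the 8 fits without 1 CB library, that of Caprin2 in 7, those of Cry1 and Klrk1 in 6 and that of Dse in 5. At all of these genes but Fcer2a and Klrk1, which were chosen as list members, the rule required that the 4 against 4 library values did not overlap.

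By camera, 8 lists stood lower in HET CB, each call lost with an estimated correlation and with few members past the test. T cell loci had 0 calls among 16 (camera adjusted p = 0.000189) and NK cell loci 1 fall among 10 (0.00193), both with an adjusted p = 0.0797 with an estimated correlation. Adjusted over the list alone, 4 fell in each. The germinal center program had 0 calls among 23 (0.00129, and adjusted p = 0.112 with an estimated correlation), with 3 falls adjusted over the list alone. Memory had 1 fall among 20 (0.00746) and naive follicular genes 1 among 14 (0.014), both with an adjusted p = 0.288 with an estimated correlation. The fall was that of Fcer2a in both lists. With p adjusted over the list alone, 4 and 2 fell. NF-kB and CD40 signaling (0.0102, and adjusted p = 0.255 with an estimated correlation), the BAF chromatin remodeling complex (0.0223, and adjusted p = 0.255 with an estimated correlation) and B lymphoma tumor suppressors and chromatin regulators (0.0422, and adjusted p = 0.288 with an estimated correlation) had 0 calls each. In each, 1 member fell adjusted over the list alone. The BAF call ended without WT CB replicate 1 (0.0937) and the tumor suppressor call with total counts (0.0523), without HET CB replicate 1 (0.0647) and without WT CB replicate 1 (0.0725) or 3 (0.151). The named members Bcl3 (-0.15, 0.0904), Arid1a, another BAF subunit (-0.16, 0.131), Arhgef1 (-0.16, 0.162), Ebf1 (-0.11, 0.165), Bach2 (-0.11, 0.177) and Tcf7 (-0.24, 0.184), did not pass, and became calls with the CB libraries fitted alone.

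Light zone (0.197), dark zone (0.516), plasma cell (0.46), MYC (0.959), cell cycle (0.249), B cell receptor signaling (0.0596), antigen presentation (0.261), interferon (0.959), myeloid (0.212), erythroid (0.516) and stromal (0.35) lists did not pass in CB. Among single genes, S1pr2 (-0.07, adjusted p = 0.788), Cd86 (-0.00, 0.985), Bcl6 (-0.11, 0.366), Cxcr4 (0.02, 0.893), Cd83 (-0.09, 0.44), Myc (0.03, 0.841), Irf4 (0.01, 0.962), Prdm1 (-0.02, 0.924), Ccr6 (-0.06, 0.694) and Spi1 (0.03, 0.879) did not pass either. Among the largest peak changes were falls of a peak 42 bp from Slc16a7 (-0.95, 7.7e-05) and peaks 106622 bp from Nabp1 (-0.81, 0.000974) and 230359 bp from Atp2b1 (-0.80, 0.000703). The rises 25419 bp from Zfp64 (0.68, 0.0242) and within Susd6 (0.50, 0.00626) were lost with the CB libraries fitted alone. A 2-level term among the CB libraries, added after the results were seen, gave 4685 peaks. It set HET replicates 1 and 3 and WT replicates 2 and 4 against the other CB libraries. This grouping was read from the residuals of these same libraries, so it lowers the spread by construction. Its count is not evidence of more changes. Leaving out 1 CB library gave between 20 (without HET CB replicate 4) and 51 peaks (without HET CB replicate 1). Slc16a7, Chrm3, Gm5127 and Chn2 were called whichever library was left out, and Fcer2a in all but the fit without HET CB replicate 4.

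In CC, heterozygous libraries were more accessible than WT at 7 of 23 germinal center genes and less accessible at 8 of 20 genes of the memory program and 7 of 14 naive follicular markers. By camera these lists passed, but with an adjusted p = 0.132 with an estimated correlation. Without HET CC replicates 2 and 4, 3 of the 29 named gene calls of this comparison stood, those of Ror2, Havcr1 and Cobll1. The calls of Gcsam, S1pr2, Fas, S1pr1, Klf2 and Satb1 rest on these replicates and ended. Gcsam rose from 55.5 ± 6.77 to 89.6 ± 19.5 CPM (mean ± SD, n = 4, log2 0.70, SE 0.11, adjusted p = 0.000629). S1pr2 rose from 48.7 ± 11.7 to 73.0 ± 10.5 (0.59, SE 0.11, 0.00218) and Fas, a death receptor of germinal center B cells, from 93.3 to 129.8 (0.49, SE 0.095, 0.00295). S1pr1, the receptor that draws lymphocytes out of tissue, fell from 461.4 ± 28.3 to 383.2 ± 31.2 (-0.27, SE 0.047, 0.000874). Klf2 (-0.29, 0.00852) and Satb1, a chromatin organizer (-0.33, 0.00118), also fell, the Klf2 call ending without WT CC replicate 2. The largest rises by the rule were at Ror2, a Wnt receptor (0.72, SE 0.1, 0.000159), Kcng2 (0.72), Havcr1, which encodes TIM-1 (0.70, SE 0.094, 9.23e-05), Gcsam and Cfap74 (0.69). The largest falls were at Cobll1, from 250.4 ± 10.4 to 169.9 ± 35.1 CPM (-0.57, SE 0.083, 0.000237), Sox4 (-0.53), Dthd1 (-0.50), Dse (-0.49) and Slc16a7 (-0.48, SE 0.088, 0.00203). The rule that chose these largest rises and falls, unlike the choice of S1pr2, Fas, S1pr1, Klf2 and Satb1 as list members or fixed names, requires that the 4 against 4 library values do not overlap.

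**Figure D2:**
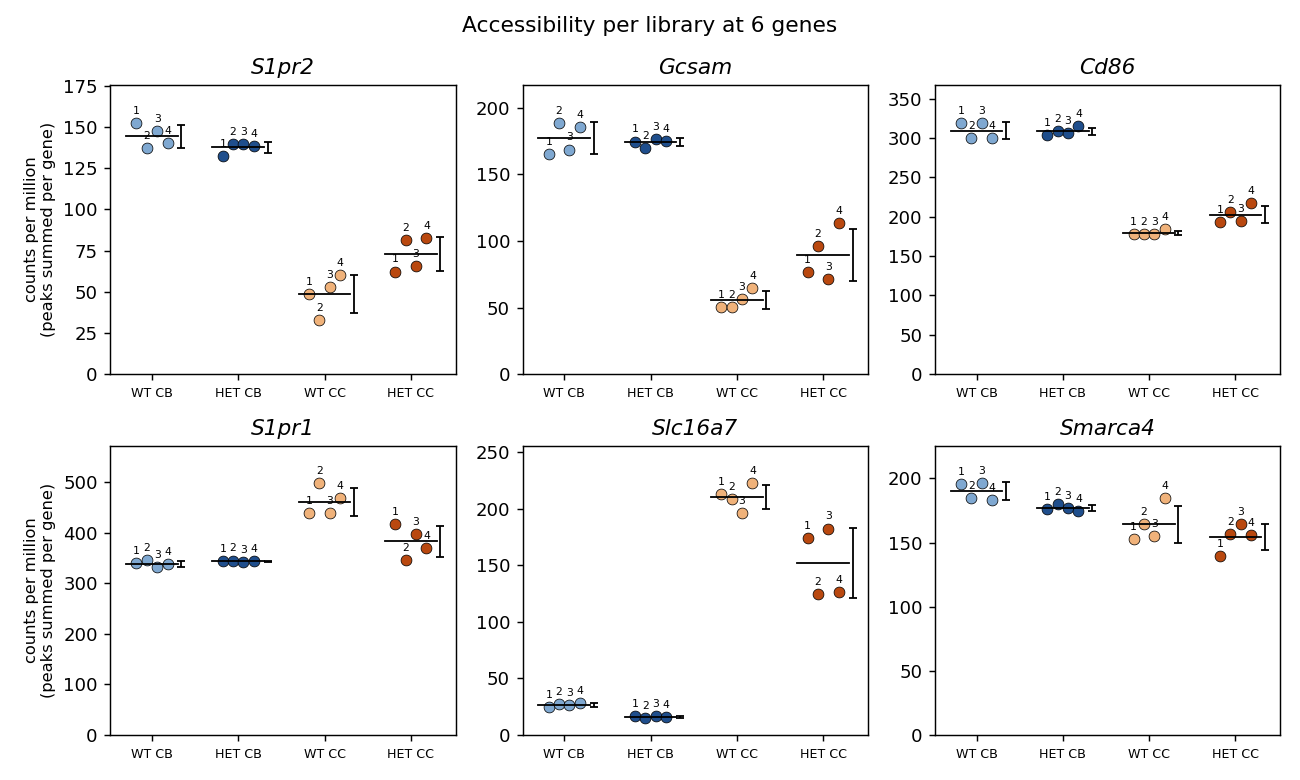
Accessibility in CPM, summed over the peaks of each gene (y axis), per library for 6 genes in WT CB, HET CB, WT CC and HET CC. Points carry the replicate number, horizontal lines are means and bars SD (n = 4).

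The germinal center program had 7 rises and 1 fall among 23 members (camera adjusted p = 0.00735, and adjusted p = 0.132 with an estimated correlation). The memory B cell program had 8 falls among 20 (3.96e-06, and adjusted p = 0.132 with an estimated correlation), Vim (-0.40, 0.00101) among them. Of these falls, those of S1pr1 and Klf2 also count in the naive list. Naive follicular B cell markers had 7 falls among 14 (2.67e-06, and adjusted p = 0.132 with an estimated correlation). T cell loci moved with them, with 5 falls among 16 (0.00663, and adjusted p = 0.132 with an estimated correlation) that included Cd3d (-0.40, 0.0168) and Cd5 (-0.35, 0.0325). The calls of Cd3d and Cd5 ended without HET CC replicate 2 and also without replicate 4. Markers of stromal and follicular dendritic cells stood lower with 0 calls among 11 (0.0371, and adjusted p = 0.132 with an estimated correlation). Adjusted over the list alone, the germinal center program had 8 rises and 1 fall, and 9 memory, 8 naive, 6 T cell and 1 stromal members fell. The stromal call ended without HET CC replicate 1 (0.119) or WT CC replicate 2 (0.0542), 3 (0.123) or 4 (0.108). NK loci did not pass (0 of 10, 0.264, median -0.239).

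The dark zone program had 3 rises among 15, Gcsam and Exo1, a DNA repair exonuclease (0.43, 0.00826), among them, and did not pass as a list (0.0689, median 0.003, mean 0.125). In the light zone list 1 member rose and 3 fell of 29 (0.0724). Cd86 rose from 179.4 ± 2.97 to 202.6 ± 11.1 CPM (0.18, SE 0.049, 0.0238). Nfkbia, the NF-kB inhibitor (-0.23, 0.00434), Rel (-0.17, 0.021) and Traf1 (-0.18, 0.0308) fell, and all of these also stand in the NF-kB list, which had 4 falls among 23 (0.0689) and 5 adjusted over the list alone. Lymphoma tumor suppressors had 3 rises and 3 falls among 27 (0.645), with Gna13 (0.17, 0.0192) and Tnfrsf14 (0.24, 0.0154) higher. The BAF complex had 1 rise, Dpf1 (0.59, 0.00524), and 1 fall, Arid1a (-0.21, 0.0282), among 28 (0.645, median -0.019, mean 0.007). Plasma cell genes had 1 rise, Jchain (0.39, 0.0184), and 1 fall among 17 (0.78), with 4 and 4 adjusted over the list alone, and cell cycle genes 1 rise, Plk1 (0.40, 0.0247), among 29 (0.557). MYC (0 of 20, 0.619, median -0.061, mean 0.004), B cell receptor (0 of 24, 0.721), antigen presentation (0 of 7, 0.725), interferon (1 and 1 of 20, 0.78), myeloid (3 rises of 15, 0.338) and erythroid (1 rise of 8, 0.319) lists did not pass. Cxcr4 (-0.00, 0.98), Cd83 (0.10, 0.198), Bcl6 (-0.01, 0.924), Myc (-0.09, 0.27), Irf4 (-0.05, 0.63), Prdm1 (-0.16, 0.0805), Ccr6 (-0.05, 0.663) and Spi1 (-0.09, 0.417) did not pass. The calls of Cd86, Rel, Traf1, Gna13, Jchain, Plk1 and Arid1a ended without HET CC replicate 2 and also without replicate 4. That of Tnfrsf14 ended without HET CC replicate 4 or WT CC replicate 2.

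In all, 889 peaks were higher and 805 lower in HET CC, and 484 and 517 genes. This fit of all 16 libraries shared a biological coefficient of variation of 8%, below the 16.4% of WT CC and 15.2% of HET CC. In simulated CC data it made 48 false gene calls and 37 false peak calls, against 4 and 3 with the CC libraries alone. Its counts are therefore not comparable between CC and CB. With each cell type fitted alone, CB gave more calls than CC. In simulated data those fits recovered 94% of 2-fold peak changes in CB and 36% in CC. Of 1.5-fold gene changes they recovered 92% and 71%. These counts therefore do not show a larger HET effect in CB. With total counts as the scaling, 1168 peaks were higher and 490 lower, and 563 and 359 genes. Leaving out 1 library gave between 338 peaks (without HET CC replicate 2) and 2991 (without HET CC replicate 3), and between 332 genes (without HET CC replicate 4) and 1435 (without HET CC replicate 3). The rises by the rule included peaks within Scn11a (2.11, SE 0.47, adjusted p = 0.0117), within Slc20a2 (1.61, 0.00372) and at Txndc5 (1.46, 0.00532). The falls included peaks 3985 bp from P2ry10 (-0.89, 0.0138) and 68300 bp from S1pr1 (-0.88, 0.00575). Of the higher peaks 12.1% (108 of 889) lay within 1 kb of a gene end, against 21.7% of uncalled peaks (Fisher exact p = 3.78e-13), and of the lower peaks 39% (314 of 805), against 21.4% (2.04e-29). Peaks of the same libraries are not independent replicates, so these p-values do not measure support across libraries. Whole libraries differed as well: HET CC held 44.6 ± 0.31% of counts near gene ends and WT CC 45.43 ± 0.38%, and 39.98 against 41.31% in the top decile of peaks (two-sided exact permutation p = 0.0286 for both, the smallest possible with 70 splits).

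Loci that rose in HET CC were mostly those that are higher in CB. With separate WT CC libraries in both contrasts, between 90.9 and 95.1% of called genes moved toward CB, against 65.1 to 67.9% of all genes. The correlation across peaks between the HET effect in CC and the change from CB to CC was -0.355 (mean of 6 splits, -0.392 to -0.321), against -0.607 with shared libraries and -0.192 in simulations of unchanged libraries that share them. On the axis from WT CC (0) to WT CB (1), HET CC libraries stood at 0.165, 0.341, 0.143 and 0.366. WT CC libraries stood at 0.035, -0.109, 0.072 and -0.005 (difference 0.256, two-sided exact permutation p = 0.0286, the smallest possible with 70 splits). The libraries farthest along the axis, HET CC replicates 2 and 4, also stood apart at an X-linked locus chosen after its values were seen. Firre, which encodes a long noncoding RNA, summed over 20 peaks, had 77 and 67.5 CPM in them, against 181.5 and 162.7 in HET CC 1 and 3 and 175.9, 168.1, 150.2 and 127 in WT CC. Without HET CC replicates 2 and 4, 1 peak and 6 genes were called, Ror2, Havcr1 and Cobll1 among them. In that fit the germinal center program (0.0173), memory B cell program (0.00893) and naive follicular B cell markers (0.00893) passed at the preset correlation and the T cell markers did not (0.14). With an estimated correlation none of these lists passed even with all libraries (adjusted p = 0.132). With the 8 CC libraries fitted alone, 186 peaks (77 higher, 109 lower) and 270 genes were called. In it Rel, Traf1, Cd86, Jchain, Plk1, Arid1a, Gna13, Tnfrsf14 and Cd5 no longer passed.

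**Figure D3:**
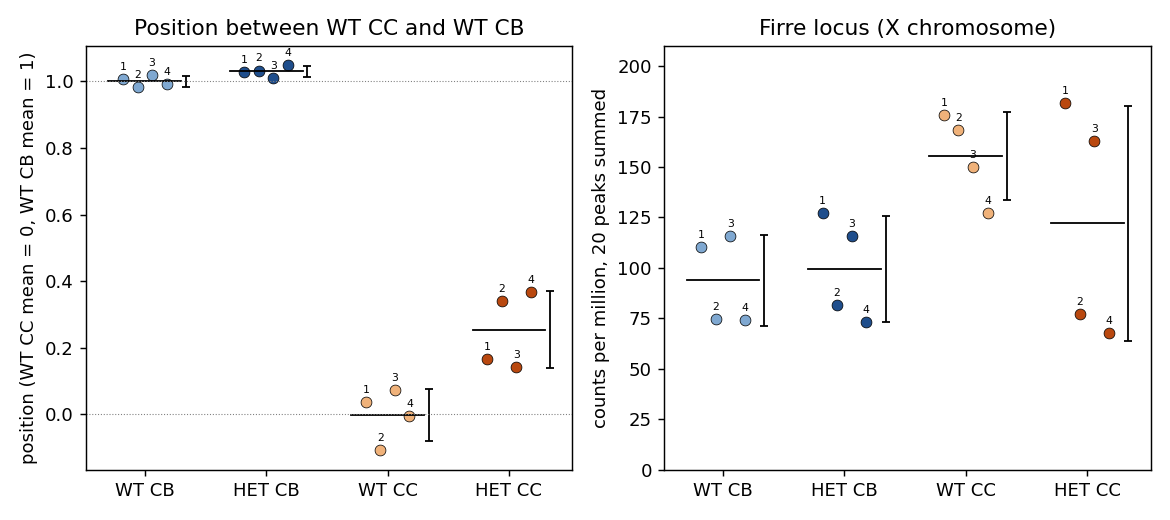
Position of each library on the axis from WT CC (0) to WT CB (1) over all peaks (left) and accessibility of the X-linked Firre locus in CPM, 20 peaks summed (right), per library in 4 groups. Points carry the replicate number, horizontal lines are means and bars SD (n = 4).

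**Figure D4:**
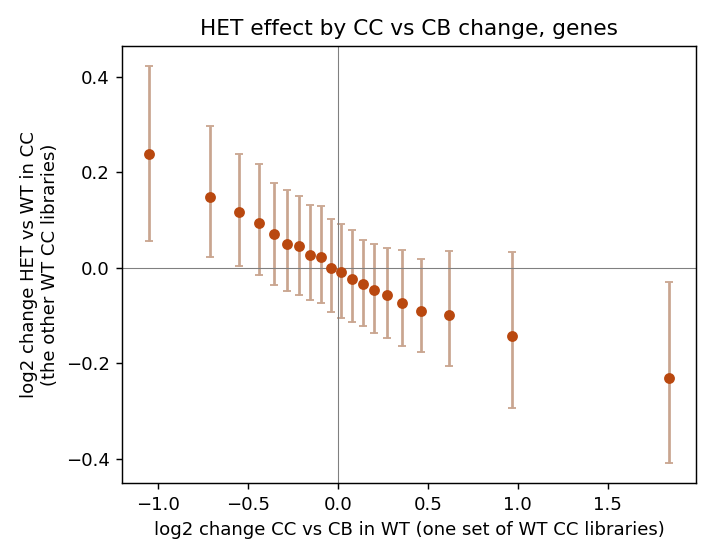
Median log2 change of HET against WT in CC (y axis) in 20 bins of genes ordered by the log2 change from CB to CC in WT (x axis), with separate WT CC libraries on the axes. Bars span the quartiles of the genes in a bin.

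The interaction test found loci at which the HET effect was more positive in CC than in CB, several germinal center genes among them, and fewer at which it was more negative. At all called genes named here HET CC lay between WT CC and WT CB. Havcr1 stood at 75.7 CPM in WT CB, 31.4 in WT CC and 50.7 in HET CC, and Gcsam at 177.1, 55.5 and 89.6. A shift of whole HET CC libraries toward CB, whose source is open, could alone give such differences. It was not told apart from an effect on these genes. Havcr1 (0.78, SE 0.11, adjusted p = 0.000199), Ror2 (0.78, SE 0.12, 0.000776), Gcsam (0.73, SE 0.13, 0.00763), C8a (0.68, 0.0141) and Atp10b (0.68, 0.00445) had the largest positive differences, with S1pr2 (0.66, SE 0.13, 0.0134), Fas (0.51, 0.0394), Ackr4 (0.58), Kcng2 (0.56) and Nuggc (0.39). Jun, a subunit of AP-1 (-0.34, SE 0.07, 0.0153), Ube2d1 (-0.33), Yipf6 (-0.33), Zc3hav1 (-0.29) and S1pr1 (-0.29, SE 0.063, 0.0212) had the largest negative ones. Calls of Havcr1, Ror2, Gcsam and Atp10b stood whichever library was left out, and those of Fas, Ube2d1, Yipf6, Zc3hav1, S1pr1, C8a, S1pr2 and Jun did not. Cd83 (0.20, 0.158), Cd86 (0.18, 0.186), Myc (-0.13, 0.407), Bcl6 (0.10, 0.618), Cxcr4 (-0.02, 0.904), Irf4 (-0.06, 0.762), Prdm1 (-0.14, 0.411), Ccr6 (0.01, 0.963) and Spi1 (-0.11, 0.537) did not pass.

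By list, the germinal center program had 5 positive and 0 negative calls among 23 (camera adjusted p = 7.8e-07, and adjusted p = 0.0363 with an estimated correlation). The dark zone program had 2 positive calls among 15 (0.017, and adjusted p = 0.0857 with an estimated correlation), a result lost without HET CC replicate 1 (0.0539) or WT CC replicate 1 (0.0614) or 3 (0.0713). Both dark zone calls also count in the germinal center program. The memory B cell program had 1 negative call among 20 (0.0018, and adjusted p = 0.306 with an estimated correlation) and the naive follicular B cell markers 1 among 14 (0.000437, and adjusted p = 0.232 with an estimated correlation). The negative call was S1pr1 in both lists. When adjusted over the list alone, 7 germinal center and 3 dark zone members were positive and 5 memory and 4 naive members negative. T cell (0.568) and NK cell (0.784) loci did not pass. In all, 105 peaks were positive and 26 negative (248 and 22 with total counts), and 53 and 9 genes. Leaving out 1 library gave between 17 (without HET CC replicate 2) and 486 peaks (without HET CC replicate 1) and between 15 and 228 genes (without the same libraries). The called peaks included positive peaks 44328 bp from Gpatch2 (1.68, 0.0303) and 169051 bp from Bcl6 (1.67, 0.0194), and negative ones near P2ry10 (-1.10, 0.0301) and S1pr1 (-0.89, 0.0453) and within Zeb2 (-0.87, 0.0386). With the replicate number as a block, the call of each of these named peaks ended. Without HET CC replicates 2 and 4, edgeR called 0 peaks (7847 at an unadjusted p below 0.05) and 2 genes, Havcr1 being the only one left of the named genes followed through the alternatives. The germinal center list stayed at 2.11e-05, and the memory (0.394) and naive (0.262) lists did not pass.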

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

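The tests of depth, of the sex of the animals behind HET CC replicates 2 and 4, of T or NK cells among the CC and of a difference over the whole X chromosome were chosen only after the results they bear on had been seen. The Firre, Xist and 4933407K13Rik loci were also picked after their values were seen.

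HET CC libraries lay nearer to the CB libraries than WT CC libraries did, by 0.256 on the axis from WT CC (0) to WT CB (1). Greater depth of the HET CC libraries, with whatever goes along with it, cannot be told apart from the genotype: replicates 2 and 4 were both the deepest of the HET CC libraries and those nearest to CB. The number of counts alone is argued against, since thinning every library to the smallest total left a difference of 0.254 and moved no library by more than 0.003. The measure does not respond to thinning, so thinning cannot judge other differences that go with depth. CB material mixed into the HET CC libraries may account for their nearness to CB, since 92.7% of the genes called with separate WT CC libraries moved toward the CB level, against 65.1 to 67.9% of all genes. A shift of the HET cells themselves could give that share as well, a biological explanation that was not tested separately. The sex of the animals behind HET CC replicates 2 and 4 cannot be told apart from a genotype effect in these libraries: replicates 1 and 3 alone lay 0.156 above WT CC (two-sided exact permutation p = 0.133 over 15 splits, too few to fall below 0.05). Apart from the number of counts alone, all of these remain open.

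Of the T cell marker loci 13 of 16 rose and 3 fell from WT CB to WT CC, and of the NK cell loci 6 of 10 rose and 1 fell (adjusted p = 0.0611 and 0.0803 with an estimated correlation). A general rise of weakly accessible loci in the CC libraries, seen as a median log2 change of 1.35 in the lowest twentieth of genes by CB accessibility, is argued against as the whole source because 100% of 10000 random lists matched on CB accessibility had a lower median than the T cell list. Fewer B cells with every other cell type alike cannot be judged from the list medians. Each less that of its matched lists, they spread over 2.02 (T 1.049, NK 2.129, myeloid 0.443, erythroid 0.109, stromal 0.937), beyond the limit set. The same added signal gives a larger log2 change where the level in CB is lower, however. Median WT CB CPM was 3.9 for NK and 11.9 for T loci, against 22.1 for myeloid, 22.7 for stromal and 25.6 for erythroid loci. T or NK cells among the sorted CC, a candidate source, would raise most of the list, and 81.2% of T cell loci were called higher, with Bcl11b at 49.5 and Cd8a at 11.5 CPM in WT CC, yet Cd2, Cd247, Cd4 and Tbx21 were lower, 0 of the T and NK members stand in another list and 3 of 16 T and 1 of 10 NK members lay above the median CB accessibility of all genes. Opening of these loci in CC themselves was not tested, and the labels give no sort gate that would exclude other cells, naive or memory B cells included.

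Loci open on the inactive X were higher in replicates 1 and 3 than in replicates 2 and 4. Firre stood at 110.4, 74.5, 116 and 74.4 CPM in WT CB 1 to 4, at 127.2, 81.7, 116 and 73.1 in HET CB and at 181.5, 77, 162.7 and 67.5 in HET CC, but at 175.9, 168.1, 150.2 and 127 in WT CC, and these pairs of replicates did not overlap in 3 of 4 groups for Firre and Xist and in 4 of 4 for 4933407K13Rik. A difference over the whole X chromosome is argued against by the other X peaks, whose median was at most 0.074 of that of the 3 loci in CB. A different sex of the animals behind the replicate numbers may account for it: the escape genes Kdm5c, Kdm6a, Ddx3x and Eif2s3x differed by a mean log2 of 0.179 in WT CB and 0.162 in HET CB, above at least 99.8% of random sets of 4 other X genes, and by 0.265 in HET CC (99.9%), but in WT CC the 0.162 lay above only 91.2%, so that group does not bear it out. The labels used here do not give the sex, and nothing says that a replicate number is an animal.

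Each comparison was refitted over 35 splits of its libraries into groups of the same sizes, the real split included, with the CB and CC libraries of a replicate number kept together in the genotype splits. For the following counts the real split alone gave as many calls (1 of 35 splits). HET against WT in CB had 106 peaks (highest other split 2), 84 genes (3) and 8 lists by camera at the preset correlation (6). HET against WT in CC had 1694 peaks (382) and 1001 genes (199), and the interaction 131 peaks (8) and 62 genes (4). The smallest share possible is 1 of 35, so these ranks argue against chance but do not exclude it. Every other genotype split mixes HET and WT libraries, so a genotype difference can enter its spread. With an estimated correlation 0 lists were called in CB and in CC against CB in WT, and fry called 0 in CB, so for lists the splits speak only to the preset correlation. Chance is not argued against for the number of lists called in HET against WT in CC (4 of 35 splits gave as many as the real 5, highest other 5) and the interaction (5 of 35, real 4, highest other 5). For CC against CB every other split mixes CB and CC within its groups, so the cell type difference enters its spread or its contrast, and these splits show no level without change. The values there were 47579 peaks (highest other 0), 9534 genes (0) and 8 lists (7) in WT, each reached in 1 of 35 splits, and 48359 peaks (0) and 9457 genes (0) in HET, also in 1. For the 7 lists in HET it was 2 of 35, where the highest other, 8, set 3 CB libraries and 1 CC library against the rest.

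The difference of the HET effect between CC and CB, tested as an interaction, passed for 131 peaks and 62 genes, among them Havcr1 (0.78), Ror2 (0.78), Gcsam (0.73), Atp10b (0.68), C8a (0.68), S1pr2 (0.66), Ackr4 (0.58), Kcng2 (0.56), Fas (0.51), Nuggc (0.39), S1pr1 (-0.29), Zc3hav1 (-0.29), Ube2d1 (-0.33), Yipf6 (-0.33) and Jun (-0.34), and for 4 lists by camera, with median log2 differences of 0.107 (germinal center), 0.032 (dark zone), -0.058 (memory) and -0.11 (naive follicular). Only the germinal center list passed with an estimated correlation (adjusted p = 0.0363), and dark zone (adjusted p = 0.0857), memory (0.306) and naive (0.232) did not. At all of the genes named here HET CC lay between WT CC and WT CB. The shift of HET CC libraries toward CB, whose source is open, could give these differences.

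In 17 of 360 groups of 4 libraries, 1 library stood apart, with a gap to the nearest other of more than 0.829 of the group's range, and chance alone gives about 1 in 20. Among WT CC libraries these were replicate 2 at Ccne1 (gap 0.838 of the range; 325.4 CPM against 288.6 to 294.5), Cobll1 (0.891; 266 against 244.2 to 246.6) and Exo1 (0.932; 28.35), replicate 4 at Cd86 (0.903; 183.9 against 177.6 to 178.2) and Fas (0.918; 114.6 against 84.73 to 87.17), replicate 3 at Prkch (0.945; 175.8 against 150.3 to 151.7) and replicate 1 at Tgfa (0.83; 28.39 against 15.38 to 17.59). Among HET CC libraries they were replicate 2 at Cd5 (0.832; 40.84 against 47.81 to 49.22), replicate 4 at Exo1 (0.888; 49.64), replicate 1 at Jun (0.87; 430.1 against 338 to 350) and replicate 3 at Plk1 (0.872; 29.02 against 39.21 to 40.7). Among CB libraries they were HET replicate 4 at Dusp14 (0.929; 132.2) and Lmna (0.977; 55.73), HET replicate 3 at Il10 (0.834; 154), WT replicate 4 at Dusp14 (0.902; 111.8) and WT replicate 1 at Tgfa (0.907; 72.3) and Yipf6 (0.942; 84.07).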

How the results depend on the processing

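Omission of HET CC replicates 2 and 4, thinning, voom with a variance weight per group, the 2-level CB term, the position covariate and the gene-end definition were chosen only after the results were seen. The 2-level CB term was read from the residuals of the libraries it was then fitted to, so it lowers their spread by construction. Motif tests, GC offsets (alone and with the replicate block) and promoter widths around transcription start sites were not run, since the genome sequence and strand were not used here. Where a value below moved and its alternative does not itself use fewer libraries, fewer counts or a stricter threshold, the cause was not tested.

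Counts of HET against WT in CB, 106 peaks and 84 genes, became 21 peaks at an adjusted p below 0.01, 5 at a minimum fold of 1.2, 647 peaks and 263 genes with DESeq2, 1076 peaks and 491 genes with the CB libraries alone, 45 peaks with the replicate block, 1645 peaks and 723 genes with voom, 4685 peaks and 2074 genes with the 2-level CB term, and 1 peak and 0 genes (797 at an unadjusted p below 0.05, edgeR) after thinning. Without 1 library they ranged from 20 to 51 peaks (HET CB 1 to 4: 51, 30, 38, 20; WT CB: 41, 36, 40, 35) and from 25 to 63 genes (HET CB 2 to 4: 31, 33, 25; WT CB: 54, 35, 48, 33; HET CB 1: 63).

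Counts of HET against WT in CC, 1694 peaks and 1001 genes, became 204 peaks at 0.01, 25 at a minimum fold of 1.2, 4662 peaks and 1647 genes with DESeq2, 186 and 270 with the CC libraries alone, 19 and 159 with voom, 803 and 667 after thinning, 1 and 6 without HET CC replicates 2 and 4, and 0 (3626 unadjusted, edgeR) and 1 with the position covariate, which itself holds the difference between genotypes. Without 1 library they ranged from 338 to 2991 peaks (HET CC 1 to 4: 2733, 338, 2991, 360; WT CC 2: 702) and from 332 to 1435 genes (HET CC 2 and 4: 361, 332; WT CC 2: 589). CC against CB in HET fell from 48359 to 31594 peaks after thinning and ranged from 44681 to 47185 without 1 library (genes 8833 to 9228), and CC against CB in WT from 44218 to 46280 (genes 8955 to 9328).

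Interaction counts, 131 peaks and 62 genes, became 270 peaks with total counts, 0 at 0.01 and 0 at a minimum fold of 1.2 (4982 unadjusted), 1413 peaks and 352 genes with DESeq2, 29 peaks with the replicate block, 0 peaks (6774 unadjusted) and 20 genes with voom, 14 and 12 after thinning, and 0 peaks (7847 unadjusted) and 2 genes without HET CC replicates 2 and 4. Without 1 library they ranged from 17 to 486 peaks (HET CC 1 to 4: 486, 17, 473, 22; WT CC 2: 20; HET CB: 57, 46, 57, 55; WT CB: 72, 75, 58, 74) and from 15 to 228 genes (HET CC: 228, 15, 220, 24; WT CC 2: 28; HET CB: 39, 29, 32, 27; WT CB: 34, 33, 39, 30).

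List calls, 8, 5, 8, 7 and 4 in the order CB, CC, WT, HET and interaction, became 0, 0, 0, 0 and 1 with an estimated correlation, 0, 10, 17 and 14 with fry in the first 4, and 1 and 3 in CB and CC with peaks as the set; without 1 library they ranged from 7 to 10, 4 to 6, 7 to 8, 5 to 8 and 3 to 5. The correlation of the HET effect in CC with the change from CB to CC was -0.607 without separate libraries. The CC position difference was 0.191 over CB-high peaks alone (exact p = 0.0571) and 0.294 over CC-high peaks alone (exact p = 0.0286). It was 0.156 without HET CC replicates 2 and 4 (exact p = 0.133). The CB position difference, 0.03, was 0.034 with total counts (exact p = 0.0286).

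Signs that reversed belonged to genes that had not passed: HET against WT in CC, Cxcr4 (0.014 with total counts, 0 with the CC libraries alone, 0.034 without HET CC 2 and 4, -0.034 to 0.032 without 1 library) and Bcl6 (0.003, 0.067 and -0.075 to 0.024 with total counts, without 2 and 4 and without 1 library); in CB, Cd86 (-0.019 to 0.012) and Irf4 (-0.01 to 0.035) without 1 library; CC against CB in HET, Cd83 (0.021 with total counts, 0.008 without 2 and 4, -0.045 to 0 without 1 library); interaction, Cxcr4 (0.014 without 2 and 4, -0.055 to 0.011), Ccr6 (-0.007 to 0.056) and Smarca4 (-0.01 without 2 and 4, -0.022 to 0.074).

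Of the named genes followed through every alternative, 29 were called in HET against WT in CC, and 3 of them without HET CC 2 and 4, 20 with the CC libraries alone and 18 whichever library was left out were still called; in CB 11 were called and 4 whichever library was left out, in the interaction 12 and 4, and in CC against CB 47 and 46 in WT and 22 and 21 in HET. In HET against WT in CC, the calls of Arid1a, Cd3d, Cd5, Cd86, Gna13, Jchain, Plk1, Rel and Traf1 ended without HET CC 2 and also without HET CC 4, that of Tnfrsf14 without HET CC 4 or WT CC 2 and that of Klf2 without WT CC 2. Of the peaks named there, those at Slc20a2 and Txndc5 and that near S1pr1 stayed called whichever library was left out. Across 210 named results, DESeq2 size factors kept direction and call of 209, total counts of 203, the DESeq2 Wald test of 202 and the replicate block of 191. The block ended the calls of Il10, Ryk, Cry1 and Klrk1 in HET against WT in CB, of Fas, Ube2d1 and Yipf6 in the interaction, and of the interaction peaks named near Gpatch2, Bcl6, P2ry10 and S1pr1 and within Zeb2. Replicate numbers were not taken as pairs. Residuals of CB and CC libraries of a number correlated at 0.034 to 0.041 in WT and 0.031 to 0.074 in HET, below the minimum of 0.1 set for pairing. Yet of the 4 numbers, libraries of a number were closest in 3 for CB with CC in either genotype, so pairing is not excluded there. Across genotypes they were closest in 0. In simulated data 51% of 2-fold peak changes were recovered in CC against 92% in CB, where both depth and the spread between replicates differ and were not varied apart.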

Other observations

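The residual structure among the CB libraries was looked at only after the results were seen.

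The HET effect in CB and in CC shared direction at some loci: across genes, which are not independent replicates, the effects correlated at 0.282, with 29 genes lower in both against 2.71 expected by chance, 3 higher in both against 0.16, and 1 opposite. Slc16a7 (-0.73 in CB and -0.48 in CC) and Dse (-0.38 and -0.49) fell in both, and their loci are among those that rise most from CB to CC in WT (2.99 and 2.77). In CB the HET effect also ran against the change from CB to CC, with a correlation of -0.366 (mean of 6 splits, -0.414 to -0.317), and HET CB lay at 1.03 ± 0.016 and WT CB at 1 ± 0.017 on the axis from WT CC to WT CB (two-sided exact permutation p = 0.0571).

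Lower peaks in HET CB lay within 1 kb of a gene end in 7.7% of cases, against 21.6% of uncalled peaks (Fisher exact p = 0.00028), whereas lower peaks in HET CC did so in 39% (2.04e-29 against 21.4%). In the interaction, 2.9% of positive peaks (6.71e-08) and 61.5% of negative peaks (1.21e-05) lay there. These Fisher tests count peaks, which are not independent replicates. Within CB, residuals after removal of the genotype means correlated at -0.05 to -0.15 between replicates 1 and 3 and between 2 and 4, and at -0.42 to -0.47 across these pairs. HET replicates 1 and 3 correlated at 0.1 to 0.12 with WT replicates 2 and 4, a structure that the labels do not name and that holds the same number of WT and HET libraries on each side.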
